A study of Homo sapiens with 10 samples.

How the data were processed

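Total RNA of whole-blood leukocytes from 5 healthy donors, each sampled before and after 5 days of G-CSF at 10 µg per kg per day, was converted to biotin-labelled cRNA and hybridized to Affymetrix U133 Plus 2.0 arrays, 1 array per sample, per the labels' protocols and the series' design text. The deposited table holds 1 linear signal intensity per probe set and array. The software that made these intensities and its scaling are not given in the sources used here. From the values, the mean of each array after trimming 2% at each end was 500.1, so the arrays share a common scale, and no further scaling was applied in the main setting. The samples' source label reads as before treatment for all 10 samples, while titles and descriptions separate 5 before from 5 after, so groups and donors were taken from the titles. No scan date or batch is given in the sources used here.

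The table has 54675 probe sets, of which 62 are controls. The annotation table supplied with the platform lists 42898 probe sets: 41097 have 1 gene symbol, 1801 have several and the remaining 11777 probe sets of the table have none here. Symbols were updated by gene ID for the 41043 single-symbol probe sets found in a RefSeq gene table, and no gene was named from a probe set with several symbols. Genes whose probe sets are unnamed here were not analysed by name. Y-linked genes, XIST and TSIX (95 probe sets) were left out of all tests. HLA-DRB, HLA-DQ and classical class I genes, KIR genes, antigen receptor segments and a few genes often deleted in the germline were tested but never named, because their level can depend on genotype. No coordinates are given.

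Intensities were transformed as log2(signal + 16), so a fold change understates that of dim genes. Probe sets with a mean at or above the 40th percentile over all arrays (log2 level 5.97) were kept, 32731 in all. limma 3.58.1 in R 4.3.3 fitted each probe set with lmFit and eBayes, with donor and treatment as terms, and p was adjusted by Benjamini-Hochberg over all probe sets, with a threshold of 0.05. Each of the 13707 genes was represented by its single-symbol probe set with the highest mean, and its adjusted p is that of the probe set. Of 1886 genes with 2 or more probe sets past the threshold, 51 had some that rose and some that fell. The pairing comes from the labels, which name the donor of each array, and the design text, which states that the same donors were sampled at both times. After centring each group, a donor's before and after arrays correlated with r from 0.083 to 0.244 across genes, over 0.1 in 4 of 5 donors, and each before array correlated best with the after array of its own donor in 5 of 5.

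The 26 gene lists, the comparisons and the rule for named genes were fixed before the data were examined. The rule took the 12 largest rises and falls among genes past the threshold with the same sign in all 5 donors, up to 3 genes per list past the threshold by size of change, and 19 genes named whatever their values. Lists were tested with camera on the gene values with a preset correlation of 0.01, adjusted over the 26 lists. With the correlation estimated from the data 0 of the 26 lists passed (smallest adjusted p = 0.246), and 3 had an unadjusted p under 0.05. fry, which asks whether the genes of a list move on balance 1 way without comparing them with other genes, passed 20 lists, and its mixed test, for changes in either direction, passed 26. Differences between lists and control ratios were tested by exact two-sided sign-flip permutation over the 5 donors, 32 sign patterns, whose smallest p is 0.0625. These 6 list differences were not adjusted for one another, since none can reach the threshold.

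The pipeline was tested on simulated data for the comparison after minus before. Of the 32735 probe sets tested there, a small part had been changed by known amounts. It recovered 0 of 66 changes of log2 0.5, 10 of 64 (15.6%) of log2 1 and 49 of 61 (80.3%) of log2 2, with 0 false calls among 59, and called 0 probe sets and 0 lists when no change was simulated. Sensitivity to small changes was therefore low where few genes change. The simulated noise was independent between probe sets, whereas the correlation estimated from the data reached 0.84 in the ribosomal list. The 0 lists called without a change therefore do not test the preset correlation of 0.01. Alternatives were no donor block, no filter, a filter at the 60th percentile, quantile normalization, centring on each array's median, offsets of 1 and 64, eBayes with trend and robust options, the mean of a gene's probe sets, leaving out each donor, an estimated correlation, fry, and lists without shared genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.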

Results

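Leukocyte RNA from venous blood of 5 healthy stem cell donors was measured before and after 5 days of granulocyte colony-stimulating factor (G-CSF) at 10 µg per kg per day. G-CSF is a cytokine that drives neutrophil production and is given to move blood-forming stem cells from the marrow into the blood. Each sample was hybridized to 1 Affymetrix U133 Plus 2.0 array, so the data comprise 5 arrays before and 5 arrays after G-CSF, from the same 5 donors. The question the design addresses is which transcripts of circulating leukocytes differ after this course of G-CSF. Every value is a level in mixed blood leukocytes, relative to the total signal of the array, and no cell counts were used here. After filtering, 32731 probe sets representing 13707 named genes were tested. The precision is limited by the number of donors.

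The arrays fell into 2 sets by treatment. Pearson correlations across genes ranged from 0.949 to 0.968 among the before arrays and from 0.944 to 0.963 among the after arrays, against 0.852 to 0.928 between the sets. Genes are not independent replicates in these correlations. The first principal component held 50.8% of the variance and separated all 5 before arrays from all 5 after arrays. The median signal of an array lay between 72.4 and 105.7, and differed by 2.82 ± 15.4 (SD of the difference, n = 5) after minus before. The log2 ratio of the 3' to the 5' control probe sets of ACTB, a measure in which degraded RNA scores higher, was 1.18 ± 0.20 before and 0.78 ± 0.21 after G-CSF (SD, n = 5), lower after in 5 of 5 donors (exact two-sided sign-flip permutation p = 0.0625, the smallest that 5 donors allow). The same ratio for GAPDH was 0.19 ± 0.07 before and 0.06 ± 0.14 after (exact permutation p = 0.25). Spiked hybridization controls had a mean log2 signal of 12.50 ± 0.08 before and 12.90 ± 0.41 after (SD, n = 5; exact permutation p = 0.125). In 1 after array these controls reached 13.58 and the 100 brightest probe sets held 14.99% of all signal, against 10.1% to 11.4% in the other after arrays. The median SD between donors was 0.317 before and 0.353 after G-CSF on the log2 scale, a ratio of 1.11 that 6 of the 16 swaps of before and after within donors matched or exceeded in size (exact permutation p = 0.375).

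After G-CSF, genes of neutrophil granules and of neutrophil and innate immune function were higher, and genes of T cells, NK cells, B cells, platelets and the interferon response were lower. These groups are lists that passed with a preset correlation between genes and did not with an estimated one (adjusted p from 0.246 to 0.413), and not every gene of a list changed: 12 of 22 innate immune genes rose and 14 of 20 interferon response genes fell. Of the 13707 genes, 1613 rose and 3326 fell at an adjusted p under 0.05, together 4939 genes or 36.0% of those tested. A change of at least 2-fold was reached by 728 of the risen and 1766 of the fallen genes. The largest rises exceeded the largest falls: 52 genes rose at least 8-fold, whereas only CCN3 and RSAD2 fell that far. All 5 donors moved the same way for 46.5% of all tested genes, where chance gives 6.25%. Among probe sets, 3498 rose and 6903 fell. The test was limma's moderated test with the donor as a block. Without donor E the counts dropped to 3153 genes, of which 972 rose and 2181 fell, and to 6450 probe sets. Without donor B, whose after array had the bright hybridization controls, 3835 genes changed.

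CD177, a glycoprotein of the neutrophil surface, showed the largest rise of all genes, by 8.86 ± 0.31 on the log2 scale (SE, n = 5, adjusted p = 1.77e-04), a 464-fold change of the signal plus 16. Its signal, back-transformed from the mean log2 level, went from 57.3 to 33958. OLFM4, a protein of neutrophil specific granules, rose by 7.45 ± 0.57, and the neutrophil collagenase MMP8 rose by 6.33 ± 0.54. The defensin DEFA4 rose by 5.53 ± 0.47, the iron-siderophore binding protein LCN2 by 5.42 ± 0.48 and neutrophil elastase (ELANE) by 5.42 ± 0.42. The palmitoyltransferase-family gene ZDHHC19 (5.27 ± 0.34), the integrin subunit ITGA7 (5.21 ± 0.19), lactotransferrin (LTF, 5.02 ± 0.66), resistin (RETN, 5.02 ± 0.23), the medium-chain fatty acid receptor GPR84 (4.72 ± 0.32) and the adhesion molecule CEACAM8 (4.68 ± 0.53) completed the 12 largest rises. The 12 largest falls shared by all donors were led by CCN3, a secreted matricellular protein, at -3.57 ± 0.29, and by the interferon-induced antiviral enzyme RSAD2 at -3.25 ± 0.49. They also included LAMP3, a lysosomal membrane protein of mature dendritic cells (-2.94 ± 0.42), the replication-fork protein RADX (-2.93 ± 0.39), MAP3K7CL (-2.90 ± 0.17), the interferon-inducible PYHIN1 (-2.87 ± 0.29), the oxysterol receptor GPR183 that positions lymphocytes (-2.81 ± 0.28) and IFIT1 (-2.80 ± 0.39). The remaining 4 were P2RY10 (-2.78 ± 0.22), the transcription factor IKZF2 (-2.69 ± 0.21), the sphingosine-1-phosphate receptor S1PR5 (-2.68 ± 0.23) and the lymphocyte adaptor SH2D1A (-2.66 ± 0.29). All errors are SEs with n = 5 donors, and the adjusted p of these 24 genes was at most 0.00412 (RSAD2).

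**Figure D1:**
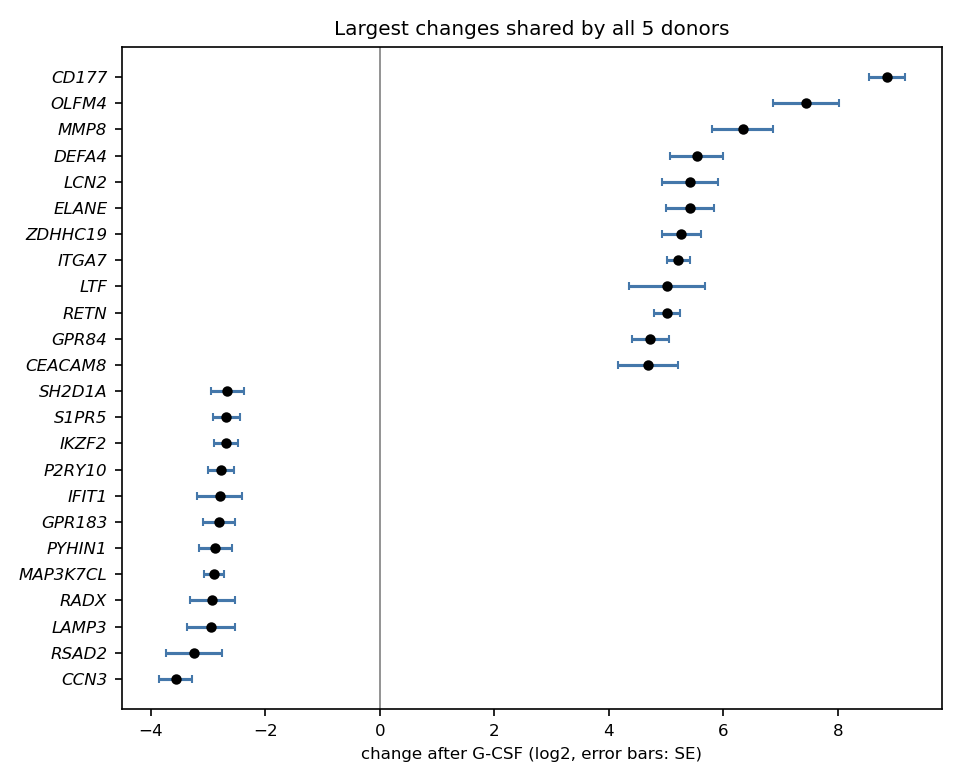
Change after G-CSF in log2 units (x axis) of the 12 genes with the largest rise and the 12 with the largest fall among genes that changed the same way in all 5 donors (y axis). Points are the fitted changes and bars their SEs; the rises run from 4.68 for CEACAM8 to 8.86 for CD177 and the falls from -2.66 for SH2D1A to -3.57 for CCN3.

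Neutrophil granule genes had the highest medians of the 26 lists. Of the 18 genes of specific and gelatinase granules, the granules formed at the later stages of neutrophil maturation, 17 rose and 0 fell, with a median change of 3.91, and the same 17 passed when adjusted over the list alone. MMP9, the gelatinase of these granules, rose by 3.25 ± 0.39 (SE, n = 5), and CHI3L1 was the member that did not pass (-0.36, named after its value was seen). Of the 10 measured azurophil granule genes, whose products are made early, at the promyelocyte stage, 9 rose and 0 fell (also 9 adjusted over the list alone), with a median of 3.76. Besides DEFA4 and ELANE these included myeloperoxidase (MPO, 4.47 ± 0.48), and the member that did not pass was lysozyme (LYZ, 0.21, named after its value was seen), which monocytes also make. Both lists stood above the other genes in limma's camera test with a preset correlation between genes of 0.01 (adjusted p = 2.51e-12 and 3.61e-08), shifting upward in 5 of 5 donors. Neither call held when the correlation was estimated from the data (adjusted p = 0.246 for both).

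Genes of the mature neutrophil rose too. Of 18 mature neutrophil surface genes, 13 rose and 0 fell, with a median change of 0.97, and 13 rose and 1 fell when adjusted over the list alone (MME, -0.76, named after its value was seen). After CD177, the tissue-nonspecific alkaline phosphatase ALPL (2.78 ± 0.21) and the Fc alpha receptor FCAR (2.57 ± 0.24) rose the most, and the G-CSF receptor CSF3R itself rose by 1.16 ± 0.19 (SE, n = 5, adjusted p = 0.00500). Of 10 S100 and cytosolic neutrophil genes 8 rose (10 adjusted over the list alone), with a median of 1.24, among them the hexokinase HK3 (3.01 ± 0.22), annexin ANXA3 (2.68 ± 0.24) and the alarmin S100A12 (1.92 ± 0.28). Of 6 genes for subunits of the NADPH oxidase, which makes superoxide, or for GTPases that activate it, 5 rose (6 adjusted over the list alone), with a median of 0.71. The subunits NCF4 (1.25 ± 0.22), CYBA (1.03 ± 0.18) and CYBB (0.77 ± 0.21) rose, together with the GTPases RAC1 and RAC2 (0.56 and 0.65, named after their values were seen). With median centring 3 of the 6 rose. CYBB passed the threshold narrowly (adjusted p = 0.0306) and lost it in leave-one-out fits without donor B, C, D or E (adjusted p from 0.0648 to 0.0900), without a filter (0.0720) and with median centring (0.0583). The camera adjusted p was 7.28e-08 for the surface list, 5.98e-07 for the S100 list and 6.23e-04 for the oxidase list. With an estimated correlation the adjusted p was 0.257, 0.246 and 0.257, so these calls did not hold either. The mean shift of the azurophil list exceeded that of the mature surface list by 2.04 ± 0.73 (SD, n = 5) on the log2 scale, in 5 of 5 donors (exact two-sided permutation p = 0.0625, the smallest that 5 donors allow).

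Of 19 genes linked to the G-CSF receptor and its STAT3 signal, 12 rose and 0 fell, with a median change of 0.91 (12 rose and 1 fell adjusted over the list alone, SOCS1 at -0.87, named after its value was seen). The list shares CD177 and CSF3R with the neutrophil surface list and LCN2 with the granule list. The adaptor GRB10 rose by 2.92 ± 0.33 and the interleukin 1 decoy receptor IL1R2 by 2.34 ± 0.43 (SE, n = 5). The feedback inhibitor SOCS3 (0.71 ± 0.53, adjusted p = 0.336, higher in 4 of 5 donors) and the high-affinity Fc gamma receptor FCGR1A (1.22 ± 0.53, adjusted p = 0.122, higher in 4 of 5 donors) did not pass. Both passed in the fit without donor A, SOCS3 at 1.29 (adjusted p = 0.0445) and FCGR1A at 1.76 (adjusted p = 0.0244). For Toll-like receptors and innate sensors, 12 of 22 genes rose and 0 fell (14 adjusted over the list alone), with a median of 0.92. The inflammasome sensors NLRC4 (2.80 ± 0.20) and NAIP (2.77 ± 0.26) and the C-type lectin CLEC4D (2.79 ± 0.32) rose the most. The lipopolysaccharide co-receptor CD14 rose by 1.54 ± 0.23 and TLR2 by 0.88 ± 0.20. Camera adjusted p was 1.89e-06 for the G-CSF list and 4.87e-09 for the innate list, and adjusted p = 0.257 with an estimated correlation for both.

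Cytokines, chemokines and their receptors moved both ways. Of 27 genes 7 rose and 3 fell (8 and 3 adjusted over the list alone), with a median change of 0.36. The receptor IL18R1 rose by 2.62 ± 0.34, whereas the neutrophil chemoattractant CXCL8 fell (-2.63 ± 0.53, adjusted p = 0.0107), as did the chemokine CCL5 (-2.31) and the receptor IL10RA (-1.04), the last 2 named after their values were seen. IL10, below the expression filter, changed by 1.01 ± 0.30 in the fit without a filter (adjusted p = 0.0692). The list's camera adjusted p of 0.0102 rose to 0.315 with an estimated correlation and to 0.0869 after quantile normalization. Of 19 glycolysis genes 12 rose and 2 fell, also when adjusted over the list alone, with a median of 0.78. HK3 belongs to this list as well, the regulatory enzyme PFKFB3 rose by 2.09 ± 0.37 and the glucose transporter SLC2A3 by 1.68 ± 0.23, and the 2 that fell were the phosphofructokinase genes PFKP (-1.39) and PFKM (-1.02), named after their values were seen. The adjusted p of the glycolysis list was 1.71e-05 with the preset and 0.257 with an estimated correlation.

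T cell markers fell throughout. All 24 measured T cell markers fell, also when adjusted over the list alone, with a median change of -2.17, and all 5 donors shifted downward. The T cell receptor complex subunit CD3D fell from a signal of 12564 to 2774, back-transformed from the mean log2 levels (-2.17 ± 0.29, SE, n = 5, adjusted p = 0.00296). The co-stimulatory receptors ICOS (-2.59 ± 0.37) and CD28 (-2.47 ± 0.26), the receptor-signal regulator UBASH3A (-2.56 ± 0.32), the adhesion receptor CD96 (-2.54 ± 0.22) and the lymph node homing receptor CCR7 (-2.02 ± 0.25) fell too. In the list of T cell receptor signalling and co-stimulation, 18 of 26 genes fell and 2 rose (19 and 2 adjusted over the list alone), with a median of -1.71. The kinase LCK, proximal to the receptor, fell as well (-2.48 ± 0.21). The 2 that rose, VAV1 (0.64) and CD58 (0.94), are used by myeloid cells too and were named after their values were seen. Of the B7 ligands that antigen-presenting cells carry, CD86 fell (-1.15 ± 0.18, adjusted p = 0.00461), and CD80 was at -0.28 ± 0.24 (adjusted p = 0.415). Leaving out the genes they share, the signalling list fell by less than the marker list, with a difference of 0.81 ± 0.28 (SD, n = 5) in 5 of 5 donors (exact permutation p = 0.0625, the smallest possible). Camera adjusted p was 3.21e-11 for the markers and 8.65e-07 for signalling, and adjusted p = 0.257 with an estimated correlation for both.

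Of 25 NK and cytotoxic lymphocyte genes 23 fell and 0 rose, also when adjusted over the list alone, with a median change of -1.96. Examples are S1PR5, the granzyme GZMK (-2.59 ± 0.30), the transcription factor EOMES (-2.45 ± 0.19) and granulysin (GNLY, -2.29 ± 0.22). Of 18 B cell markers 15 fell and 0 rose (16 adjusted over the list alone), with a median of -1.55. The adaptor BANK1 (-2.07 ± 0.19), the B lineage transcription factor EBF1 (-1.95 ± 0.24) and MS4A1, which encodes CD20 (-1.95 ± 0.19), fell the most. The camera adjusted p was 7.99e-11 for the NK list and 4.50e-06 for the B cell list, against an adjusted p of 0.246 and 0.280 with an estimated correlation. T cell markers fell further than B cell markers in 5 of 5 donors, by -0.71 ± 0.31 (SD, n = 5; exact permutation p = 0.0625, the smallest possible). The difference between T cell and NK markers was -0.27 ± 0.34, with the same sign in 4 of 5 donors (exact permutation p = 0.1875), within the spread between donors.

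**Figure D2:**
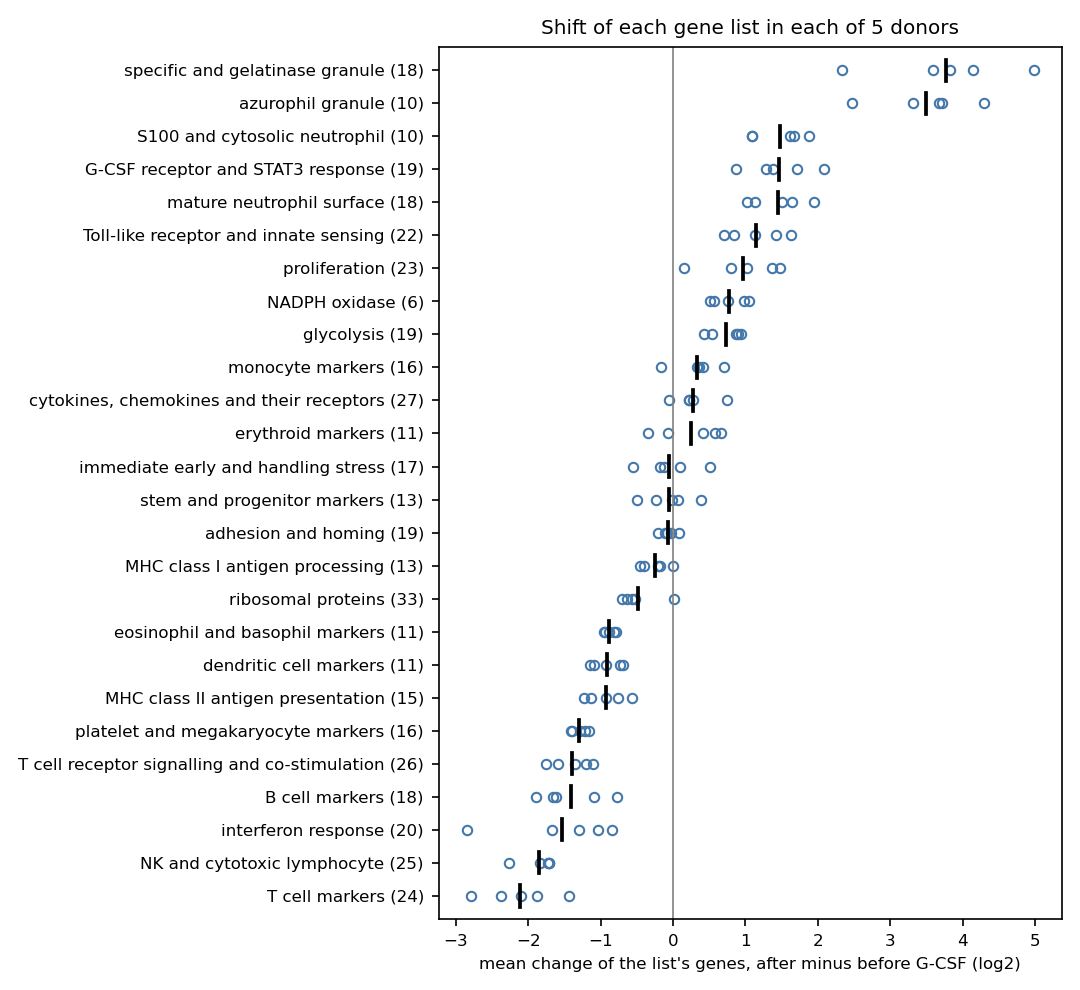
Mean change after minus before G-CSF, in log2 units (x axis), of the measured genes of each of the 26 lists fixed in advance (y axis, number of measured genes in parentheses). Each circle is 1 donor and each bar the mean of 5 donors; the T cell markers lie between -2.79 and -1.44 and the azurophil granule genes between 2.47 and 4.29.

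MHC class II genes, which serve presentation of antigen to helper T cells, were lower after G-CSF. Of 15 genes 11 fell and 1 rose (11 and 2 adjusted over the list alone), with a median change of -1.13 and a downward shift in 5 of 5 donors. HLA-DPB1 (-1.71 ± 0.20), HLA-DOB (-1.67 ± 0.20), HLA-DRA (-1.29 ± 0.18) and the invariant chain CD74 (-1.06 ± 0.19) fell. CIITA, the master transactivator of the class, fell on its brightest probe set (-1.49 ± 0.21), while the mean of its probe sets was at -0.38 (adjusted p = 0.295). The member that rose was the transcription factor subunit RFXANK (0.81, named after its value was seen). The mean shift of the class II list was -0.92, against 0.33 for the monocyte list, a difference of -1.25 ± 0.44 (SD, n = 5), and against -1.41 for the B cell list, a difference of 0.48 ± 0.30, each of the same sign in 5 of 5 donors (exact permutation p = 0.0625 for both). The smallest difference of a donor from the B cell list was 0.0048, close to none. For MHC class I processing, 2 of 13 genes fell, ERAP1 (-1.16 ± 0.17) and TAP2 (-1.07 ± 0.17), and 1 rose, TAPBP (0.54 ± 0.17, adjusted p = 0.0494). Adjusted over the list alone, 2 fell and 0 rose, and after quantile normalization 5 fell and 0 rose over all genes tested. The TAP2 change was -0.28 on the mean of its probe sets (adjusted p = 0.183). TAPBP did not pass without the donor block (adjusted p = 0.252) nor without any single donor (adjusted p from 0.0711 to 0.126), and 5 other settings gave 0.0583 to 0.297. The class II list had a camera adjusted p of 0.00232, and 0.315 with an estimated correlation. The class I list did not pass with camera (median -0.31, adjusted p = 0.507).

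Monocyte markers showed a small and unstable shift. Of 16 genes 5 rose and 1 fell, also when adjusted over the list alone, with a median change of 0.16. CD14, the membrane protein MS4A6A (1.26 ± 0.19) and the scavenger receptor MARCO (1.24 ± 0.30) rose, as did CD93 (1.09) and LILRB2 (0.87), and MS4A7 fell (-0.66); the last 3 were named after their values were seen. MARCO did not pass in the leave-one-out fits without donor B, C, D or E (adjusted p from 0.0534 to 0.0670) nor without the donor block (0.184). The list's adjusted p of 0.0464 became 0.463 with an estimated correlation and 0.262 after quantile normalization, and the call also ended without donor B (0.0568), C (0.0669) or D (0.227). Of 11 dendritic cell markers 6 fell and 0 rose (7 adjusted over the list alone), with a median of -0.72, led by CD1C (-2.39 ± 0.27), FCER1A (-2.26 ± 0.27) and TLR7 (-1.56 ± 0.33). Of 11 eosinophil and basophil markers 6 fell and 0 rose, also when adjusted over the list alone, with a median of -0.95. Among them were SIGLEC8 (-1.83 ± 0.34), ALOX15 (-1.39 ± 0.29) and the interleukin 5 receptor IL5RA (-1.29 ± 0.23). The dendritic and the eosinophil and basophil lists each had a camera adjusted p of 0.0148, and an adjusted p of 0.246 with an estimated correlation. The eosinophil and basophil call also ended under the stricter filter (adjusted p = 0.0585).

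Platelet and megakaryocyte genes fell in 13 of 16 cases and rose in 0 (15 and 1 adjusted over the list alone, CLU rising by 1.29, named after its value was seen), with a median change of -1.32. GNG11 (-2.52 ± 0.24), the platelet tubulin TUBB1 (-2.46 ± 0.19) and the chemokine PF4V1 (-2.16 ± 0.24) fell the most. The platelet list had a camera adjusted p of 6.94e-06, and 0.246 with an estimated correlation. Erythroid markers did not pass as a list (median 0.22, adjusted p = 0.216). Of its 11 genes the globin HBD (1.47 ± 0.29) and the carbonic anhydrase CA1 (1.01 ± 0.24) rose and TRIM58 fell (-0.86 ± 0.21), also when adjusted over the list alone. HBD and CA1 did not pass without the donor block (adjusted p = 0.136 and 0.0858), and CA1 not without donor C (0.0562). TRIM58 lost its call without donor A, B or C (adjusted p from 0.0516 to 0.0581), without a filter (0.0538), after quantile normalization (0.0831) and on the mean of its probe sets (0.0876). Without donor B the erythroid list passed, with a median of 0.51 (adjusted p = 0.0131).

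Stem and progenitor markers, genes of the cells that G-CSF is given to mobilize, did not shift as a list. As levels in mixed leukocytes, they do not tell whether the number of such cells changed. Of 13 genes 3 rose and 5 fell, also when adjusted over the list alone, and the median of -0.36 and the mean of -0.06 were below 0 while camera's direction was upward (adjusted p = 0.939). The median ran from -0.55 to -0.06 in leave-one-out fits and was 0.18 without genes in more than 1 list. CD34, the surface marker used to count mobilized cells, lay below the expression filter. Its signal, back-transformed from the mean log2 level, was 44.9 before and 47.6 after. It changed by 0.06 ± 0.56 in the fit without a filter (SE, n = 5, adjusted p = 0.955). The transcription factors ERG (2.59 ± 0.41) and, named after their values were seen, MYB (1.16) and LMO2 (0.70) rose. MEIS1 (-1.68 ± 0.31), the cyclin-dependent kinase CDK6 (-1.31 ± 0.22) and, also named afterwards, KIT (-1.21), GATA2 (-0.95) and SOX4 (-0.91) fell. The adhesion and homing list did not pass (adjusted p = 0.162), with 5 of 19 genes rising and 5 falling (6 and 5 adjusted over the list alone), a median of 0.26 and a mean of -0.06; the median was 0.065 after quantile normalization and 0.127 without donor E. CXCR4, which retains stem cells and neutrophils in the marrow, was at 0.26 ± 0.21 (adjusted p = 0.378, higher in 3 of 5 donors). CCR7, ICAM2 (-1.94 ± 0.17), the lymphocyte egress receptor S1PR1 (-1.50 ± 0.24), and the integrin subunits ITGA4 (-1.08) and ITGB1 (-0.74) were the 5 that fell. Those that rose were the leukocyte integrin subunit ITGB2 (1.06), ICAM1 (0.90), CD44 (0.82), SELPLG (0.79) and CCR1 (0.59), which were named after their values were seen, as were ITGA4 and ITGB1.

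**Figure D3:**
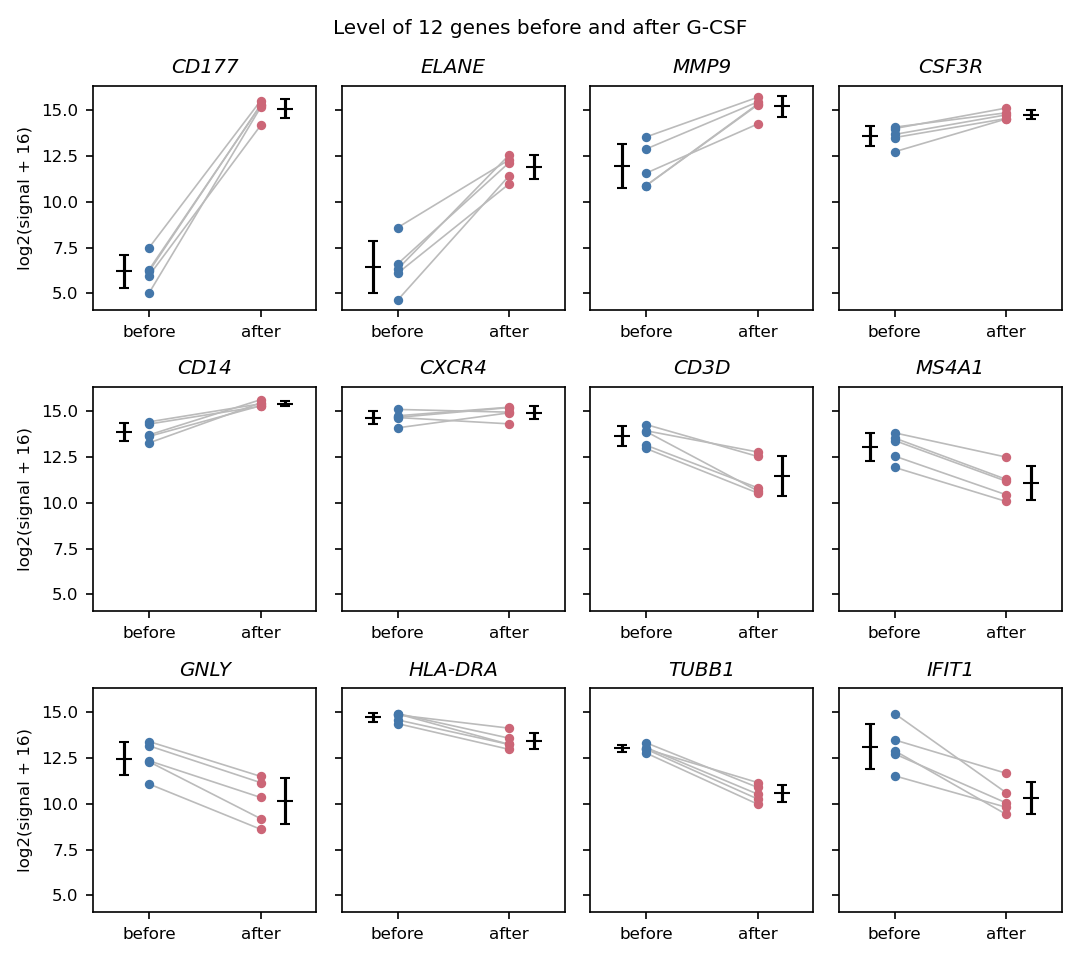
Level, as log2 of the signal plus 16 (y axis), of 12 genes before and after G-CSF; each dot is 1 array, lines join the arrays of a donor, and the bars beside the dots are the mean and SD of 5 donors. CD177 rose from a mean of 6.20 to 15.05, CXCR4 had means of 14.63 and 14.89, and CD3D fell from 13.62 to 11.45.

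Cell division genes rose more often than they fell. Of 23 genes of the proliferation list 14 rose and 1 fell (16 and 1 adjusted over the list alone), with a median change of 1.17. The mean of this list moved by 0.80 to 1.48 in 4 donors and by 0.16 in donor B. The ribonucleotide reductase subunit RRM2 (2.31 ± 0.32), thymidylate synthase (TYMS, 2.25 ± 0.29) and the cyclin CCNB2 (1.88 ± 0.21) rose the most, and the replication helicase subunit MCM3 fell (-0.84, named after its value was seen). Interferon response genes moved the other way, with 14 of 20 falling and 0 rising, also when adjusted over the list alone, and a median of -1.80. RSAD2, IFIT1 and IFIT3 (-2.65 ± 0.24), all induced by type I interferon, fell the most. The mean shifts of the 5 donors in this list ranged from -2.85 to -0.84, with an SD of 0.79, against 0.51 for the T cell markers. Ribosomal protein genes fell in 11 of 33 cases and rose in 0 (12 adjusted over the list alone), with a median of -0.43; after quantile normalization 27 fell, with a median of -0.63. The mean of the list moved by -0.70 to -0.52 in 4 donors and by 0.0097 in donor B, whose after array had the bright hybridization controls. Examples are RPL22 (-0.93 ± 0.16), RPL35 (-0.92 ± 0.17) and RPL3 (-0.89 ± 0.17). Camera adjusted p was 3.67e-06 for proliferation, 1.10e-04 for the interferon list and 2.52e-04 for the ribosomal list, and with an estimated correlation the adjusted p was 0.315, 0.413 and 0.513. Immediate early and handling stress genes, which respond within minutes to blood handling, did not pass as a list (adjusted p = 0.234). Of 17 genes 4 rose and 3 fell, also when adjusted over the list alone, with a median of 0.23 and a mean of -0.05. After quantile normalization 2 rose, with a median of 0.035. EGR1 (1.66 ± 0.49) and, named after their values were seen, NFKBIA (1.13), IER3 (0.97) and JUNB (0.70) rose, and CXCL8, DUSP2 (-1.53 ± 0.19) and ATF3 (-0.97, also named afterwards) fell. EGR1 passed narrowly (adjusted p = 0.0384) and not without donor A, B, D or E (adjusted p from 0.0665 to 0.112), nor in 5 other settings (0.0539 to 0.0738).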

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

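Of 264 sets of 5 values examined, namely list levels, array measures and named genes in each group, 13 had an end value far from the other 4, where chance gives about 1 in 20 sets, or 13.2. Of these 10 were after G-CSF, and 8 lay on the after array with the brightest hybridization controls. Genes and lists are not independent of each other, so whether 8 on 1 array exceeds chance was not tested. Without the donor of that array, 3835 genes changed. After G-CSF, that array had 14.99% of its signal in the 100 brightest probe sets, against 10.1% to 11.4% in the others. Among list levels after G-CSF, the end values were 9.22 for T cell receptor signalling, against 8.54 to 8.69, and 15.43 for ribosomal proteins, against 14.67 to 14.80. Single genes after G-CSF with a low end value were CD177 at 14.14, against 15.13 to 15.49, MMP8 at 13.00, against 14.43 to 14.60, MMP9 at 14.22, against 15.26 to 15.68, GRB10 at 9.60, against 11.18 to 11.72, and FCGR1A at 5.21, against 7.09 to 7.38. High end values after G-CSF were 17.00 for S100A12, against 16.12 to 16.37, and 14.48 for RPL35, against 13.66 to 13.85. Before G-CSF, the dendritic cell markers had 1 array at 8.56, against 8.88 to 8.99, CXCL8 had 1 at 10.08, against 13.88 to 15.10, and S1PR1 had 1 at 11.95, against 10.80 to 11.06. All are log2 levels, apart from the share of signal.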

How the results depend on the processing

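No called list and no gene named by the rule fixed beforehand reversed its direction under the settings run; the stem and progenitor list, which did not pass, had camera's direction upward as deposited and downward after quantile normalization (adjusted p = 0.953). The share of changed genes that fell lay between 60.4% (quantile normalization) and 70.9% (median centring), against 67.3%, and the median change of all genes was -0.12 as deposited, -0.05 and -0.15, and 0.01 with no filter. The fit with no replicate block changed 4846 genes, of which 4446 were among the 4939 of the paired fit, and ended the calls of the monocyte list and of 5 such genes (TAPBP, MARCO, HBD, CA1, EGR1) and of no other list or gene named by that rule. Counts of changed genes ran from 3466 (no filter, where more dim probe sets are tested) to 5915 (trend and robust variance) with all donors. In leave-one-out fits they ran from 3153 to 4283 genes, 972 to 1392 higher, 2181 to 2891 lower, and 6450 to 8834 probe sets, with donor E giving the lowest; fewer samples alone lower such counts. All 21 lists called with a preset correlation of 0.01 lost the call with an estimated correlation, which leaves their medians as they were: azurophil granule 3.76, specific and gelatinase granule 3.91, mature neutrophil surface 0.97, S100 and cytosolic 1.24, NADPH oxidase 0.71, G-CSF and STAT3 0.91, Toll-like receptor 0.92, cytokines 0.36, glycolysis 0.78, proliferation 1.17, monocyte 0.16, T cell -2.17, T cell receptor signalling -1.71, B cell -1.55, NK -1.96, MHC class II -1.13, dendritic -0.72, eosinophil and basophil -0.95, platelet -1.32, interferon -1.80 and ribosomal -0.43. With that setting the adjusted p of these lists ran from 0.246 to 0.513; the cause was not tested. The cytokine list also lost its call after quantile normalization (0.28, adjusted p = 0.0869) and with fry (0.36, adjusted p = 0.0890), and the MHC class I list gained one with fry (-0.31, adjusted p = 0.0466). The monocyte list lost its call with no replicate block, no filter, fry, or without genes in more than 1 list (0.16 in each), under the stricter filter (0.037), quantile normalization (0.018), with the mean of all probe sets of a gene (0.20), and in 3 of the 5 leave-one-out fits (over all 5 of them, 0.056 to 0.40). The stricter filter ended the eosinophil and basophil call (-0.95, adjusted p = 0.0585). The erythroid list, at 0.19 to 0.51 in leave-one-out fits, passed only without donor B. After quantile normalization 27 ribosomal genes fell in place of 11, 5 MHC class I genes fell and 0 rose in place of 2 and 1, and 2 immediate early genes rose in place of 4; with median centring 3 NADPH oxidase genes rose in place of 5. Where no construction is named, the cause was not tested. Dim genes are limited by the offset of 16, below which 14.5% to 22.5% of the probe sets of an array lay.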

Other observations

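Genes grouped by the letters of their symbols, a grouping made after the data were seen, add 3 families to the lists. Of 196 families with at least 8 tested genes and none on a list, 3 passed camera with the preset correlation, all downward, and 0 passed with an estimated correlation (4 at an unadjusted p under 0.05). Genes named ZNF, mostly zinc finger transcription factors but with pseudogenes and antisense RNAs among them, fell in 167 of 415 cases and rose in 16, with a median change of -0.57 (adjusted p = 1.88e-04, and adjusted p = 0.734 with an estimated correlation). Genes for proteins of the small mitochondrial ribosome subunit (MRPS) fell in 16 of 27 cases and rose in 0, with a median of -0.61 (adjusted p = 0.00574, and 0.734 with an estimated correlation), led by MRPS33 (-1.55). Genes named MRPL, which are those of the large subunit and 1 antisense RNA (MRPL20-AS1), fell in 20 of 49 cases and rose in 1, with a median of -0.52 (adjusted p = 0.00816, and 0.778 with an estimated correlation), led by MRPL1 (-1.48). The mean of each family was lower after G-CSF in 5 of 5 donors. Their medians were -0.42, -0.45 and -0.33 after quantile normalization and -0.60, -0.63 and -0.55 with median centring. All genes also leaned downward: of the 13707 tested, 3326 fell and 1613 rose. The median change of all genes was -0.12 as deposited, -0.05 after quantile normalization and -0.15 with median centring.

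The differences between lists, the leave-one-out fits and the estimated correlation were planned, but what they would show under each explanation was written after the results were seen, as were all other tests of explanations except those of dim probe sets and of shared B cell genes. Among the 16 splits of the 10 arrays that part every donor's pair, only 1, the real one with 4939 genes, gave as many changed genes, and the highest of the others gave 0 with limma; 16 splits are too few for a share under 0.05. Another 84 splits, drawn at random from those that leave at least 1 pair on the same side, also gave 0. At an unadjusted p under 0.05 the real split gave 6553 genes and the highest of the others 4260. A count of 0 in such splits also reflects the real difference, which inflates the spread within each side.

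T cell markers fell further than B cell markers, which bears on whether lymphocytes as a whole were only diluted by other cells. A lower share of all lymphocytes alike would move both lists by the same amount only if their genes were alike in background and in use by other cells. They parted by -0.71 ± 0.31 (SD between donors) in 5 of 5 donors. The T cell receptor signalling and T cell marker lists also parted, by 0.81 ± 0.28 in 5 of 5 donors. The signalling list, however, holds genes that myeloid and antigen-presenting cells use, such as VAV1, CD58 and CD86. Its gap therefore does not tell how much of the gap between T and B cell markers comes from list make-up. A lower share of all lymphocytes alike cannot be excluded. Compression of fold changes in dim probe sets would remove the gap among bright members, where it was -0.75 ± 0.35 (18 T and 7 B cell genes), in 5 of 5 donors. B cell genes used by other blood cells would hold the B list up, but with the 10 most restricted ones the gap was -0.90 ± 0.32, and -0.59 ± 0.18 in 5 of 5 donors with the 8 of them that fell, leaving out FCRL1 and CR2. A hypothesis that stays open is that T cells, or their transcripts per cell, may have dropped more than B cells; the exact permutation test of 5 donors cannot pass 0.05.

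Azurophil granule genes rose further than mature neutrophil surface genes, by 2.04 ± 0.73 (SD between donors) in 5 of 5 donors. More neutrophils of an unchanged kind would raise all their genes alike only if the genes were alike in background and in use by other cells. Among the 11 members with a before level under log2 11 (8 azurophil and 3 surface genes) the mean changes differed with an SD between genes of 1.83. It was 1.08 without CD177 and 1.37 in the 4 with a before level of at least log2 8. For each, p = 0.0001, the smallest that the permutations of genes within donors allow. Most of the 11 genes began near the floor, where unequal background can make equal rises look unequal. The mean before levels of those 4 lie clear of it, although DEFA4, at 8.49, had an SD of 1.66 between donors. The 4 genes rose unequally, by 2.57 to 5.53, and the offset shrinks rises of dim genes rather than enlarging them. Whether more neutrophils of an unchanged kind gave this cannot be told. The rule for this test asked for at least 5 genes clear of the floor, and use by other cells was not measured. More neutrophils together with another change cannot be excluded. Whether saturation of bright probe sets widened the gap between the lists cannot be told. Among the 11 members with a before level under log2 11 the gap was -0.64 ± 0.75, above 0 in 1 of 5 donors. It was 1.42 ± 0.60 in 5 of 5 donors without CD177, left out after its value was seen. Among members with a mean level under log2 13 and under log2 14, limits chosen after the values of the genes were seen, the gap was 1.16 ± 0.83 and 1.92 ± 0.79, in 5 of 5 donors each. Without CD177 it was 2.39 ± 0.79 and 2.61 ± 0.77, also in 5 of 5 donors each. Dividing precursors in the blood cannot be told apart from other sources of granule transcripts, since every value is a level in mixed leukocytes. The proliferation list rose in camera with the preset correlation and had an adjusted p of 0.315 with an estimated one. With an estimated correlation 0 of the 26 lists passed, so that value does not bear on the source.

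Interferon response genes fell, with donors shifting by -2.85 to -0.84. Donor D, with the largest fall, started high. Its list mean was 13.27 before G-CSF, against 10.70 to 11.60 in the other donors. After G-CSF it was 10.43, within the range of 9.66 to 10.76 of the others. A single donor does not carry the fall, since the median nearest to 0 with a donor left out was -1.43 and the list passed each time with the preset correlation, although with all donors its adjusted p was 0.413 with an estimated correlation. Poorer RNA after G-CSF would raise the 3' to 5' ratio of ACTB, which instead changed by -0.40 ± 0.17 (SD) and was lower in 5 of 5 donors. The ratio of GAPDH changed by -0.13 ± 0.17 (SD) and was higher after G-CSF in 2 of 5 donors. Fewer lymphocytes cannot be told apart from a lower response per cell: the list fell less than the T cell markers, with a difference of 0.58 ± 0.50 that was below 0 in 1 of 5 donors, and many cell types use these genes. A candidate explanation that stays open, with no test here, is a lower interferon signal after G-CSF.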
